A study of Mus musculus with 16 samples.

How the data were processed

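Gene expression was measured by RNA sequencing of total RNA from colonic epithelial cells of mice in 16 libraries, 4 for each of the groups control and cKO on normal water and control and cKO after 3% DSS. Groups and replicate numbers were taken from the labels. Per the labels' protocols, reads that held adapters, undetermined bases or low quality were removed. Per the submitters' processing notes, the authors used featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mm10 genome build; the aligner and the annotation release are not given in the sources used here, nor is the counting stated to use strand, so overlapping and antisense genes may share reads. The deposited values are FPKM (fragments scaled to gene length and library size) for 56268 genes with their positions and lengths, in 1 column per library.

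FPKM multiplied by the deposited gene length came out in whole multiples of a step in each library, within 0.05 for at least 99.995% of the values above 0, which gave back the reads behind each value. Recovered reads came to 13911824 to 16414916 per library, with 19969 to 22738 genes above 0, and 4.74 to 15.1% of reads from mitochondrial genes. FPKM totals implied scaled library sizes 0.95 to 1.06 times the sum over the genes. No 2 libraries of the same group agreed within counting noise. At this depth a gene near 1 FPKM rests on few reads, so low genes are measured less precisely.

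Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 4 libraries were kept, 13255 in all. A model with a mean for each of the 4 groups was fitted to all 16 libraries, so that the groups share an estimate of the spread per gene, with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), and the two-sided moderated test was adjusted by the Benjamini-Hochberg method within each of 5 comparisons: genotype on water, genotype after DSS, DSS in control, DSS in cKO, and the interaction. Genes at an adjusted p under 0.05 were called, with no fold limit. Rictor was also tested with an exact two-sided permutation test of FPKM. 40 gene lists were fixed before the data were examined, covering mTOR signalling, epithelial and other cell types, immune responses, metabolism and stress. The 35 with at least 5 kept members were tested with camera at its preset correlation of 0.01 and adjusted over the lists of a comparison; camera with an estimated correlation and fry (with statmod 1.5.0) were alternatives. Fry tests whether the genes of a list move one way on balance, without comparing them with other genes. A list's median and its test differed in sign in a few lists that were not called.

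The genes named were chosen by a rule fixed before the data were examined: Rictor and the mTOR complexes; in each comparison the 10 largest rises and falls among called protein-coding genes whose 4 values in a group all lay beyond those of the other group, leaving out predicted genes and antigen receptor segments, with the smallest p given as values where fewer than 5 passed; the 10 smallest p for the interaction; and the 2 to 4 members with the smallest p of each list. The share of genes whose groups did not overlap was 15.5, 10.0, 28.3 and 19.1% in the genotype and DSS comparisons, in the order above, where chance gives 2.86%.

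The test was tried on simulated reads drawn from the real means and library sizes for the DSS comparison in control, on 12971 genes. It recovered 39.7% of genes changed 1.5-fold, 87.7% of those changed 2-fold and all of those changed 4-fold, with 7 false calls of 154. With a GC trend put into the libraries, on 12969 genes, false calls rose to 47 of 187 and a GC correction brought them to 6 of 154. All genes and libraries were simulated with the same spread beyond counting noise (dispersion 0.0166), and the GC trend was linear. The rates therefore do not cover genes or libraries with a wider spread, or other GC effects. A list changed 1.3-fold was called in a simulated genotype comparison on water, and 0 of 33 others were. Simulated genes were drawn independently of each other, while real lists were correlated, with an estimate of 0.62 for type I interferon. The simulation therefore does not show how often unchanged real lists are called.

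Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, a shift of medians, sample quality weights, a replicate block, fits on the 8 samples compared, limma voom on the recovered reads, a fold limit, and leaving out each library. Chosen after seeing the data were a correction of each library for GC content (of the longest transcript per gene in GENCODE M21, known for 97.1% of the kept genes) by loess with a span of 0.5, the same for gene length, both together, the Y-linked level as a covariate, and fits without cKO_DSS 3 and 4 or without control 4 and control_DSS 2. The labels give no sequencing batch or date.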

Results

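RNA sequencing measured gene expression in colonic epithelial cells of mice. The cells came from control mice, which carried the Villin-Cre transgene that drives Cre recombinase in intestinal epithelium, or from conditional knockout (cKO) mice, in which Villin-Cre deletes the floxed Rictor gene. Rictor is the defining subunit of mTOR complex 2 (mTORC2), a kinase complex that phosphorylates AKT, SGK and PKC kinases. Mice of each genotype received normal water or 3% dextran sulfate sodium (DSS), a polysaccharide that injures the colonic epithelium and induces colitis. Each of the 4 groups held 4 libraries, 16 in all, with 13911824 to 16414916 reads per library recovered from the deposited FPKM values. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples. Control 3, cKO 3 and cKO 4 held 0 reads of 4 Y-linked genes. The other control libraries held 648 to 1377, and cKO 1 and 2 held 635 to 1856. Xist, expressed in female cells, had 5275 reads in control_DSS 2 and 1 to 7 in the other control_DSS libraries. These values argue against a spread that is technical alone in those groups. In cKO_DSS the spread may be technical. The study asked how mTORC2 signalling in the epithelium bears on colitis, and its design compared the genotypes on water, the genotypes after DSS, and DSS with water. Below, a gene was called when its adjusted p from limma was under 0.05, and fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

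Rictor, on mm10 chromosome 15 from 6708379 to 6800401, was measured at 2.80 ± 0.44 FPKM in control libraries and 2.47 ± 0.24 FPKM in cKO libraries on water (mean ± SD, n = 4 each). The cKO mean was 88.2% of the control mean, a difference within the spread between samples (log2 fold change -0.13 ± 0.12 SE, adjusted p = 0.582; exact two-sided permutation p = 0.257). After DSS, Rictor was 3.63 ± 0.57 FPKM in control libraries and 2.51 ± 0.46 FPKM in cKO libraries. The cKO mean was 69.0% of the control mean, and the difference did not pass either test (log2 fold change -0.40 ± 0.12 SE, adjusted p = 0.0761; exact two-sided permutation p = 0.0571, where the smallest p this design allows is 0.0286). Under limma voom on the recovered reads the difference after DSS passed the threshold, at -0.54, and so it did without control_DSS replicate 3, at -0.49, or without cKO_DSS replicate 1, at -0.46. FPKM here cover the whole gene and no exon values were used, so transcripts that lack only the deleted exons still count, and these values are an incomplete check of the genotype labels. Of the 11 measured members of the mTOR complex list, none was called between genotypes on water or after DSS, and 1 was called after DSS when adjusted over the list alone.

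**Figure D1:**
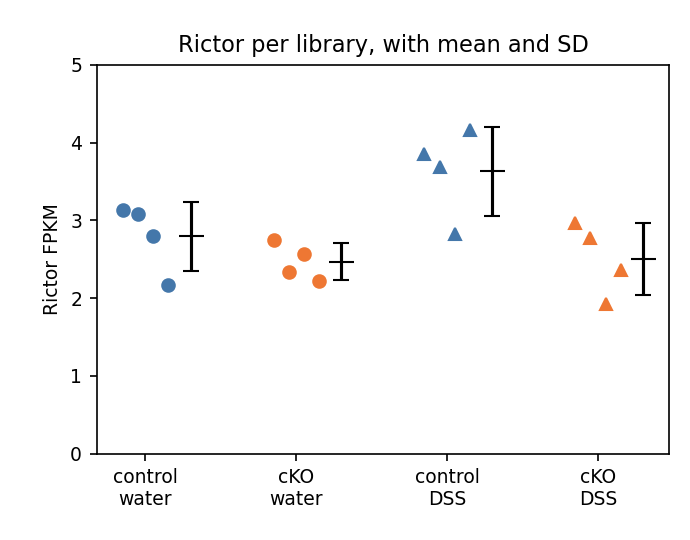
FPKM of Rictor (y axis) in each library of the 4 groups (x axis), with the group mean and SD (n = 4) beside the points. Group means were 2.80, 2.47, 3.63 and 2.51 FPKM, and the cKO and control libraries overlapped on water.

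On water, 12 of 13255 genes differed between genotypes, 7 higher and 5 lower in cKO, and 2404 had an unadjusted p under 0.05. Ly6g6c, a member of the LY6 family of membrane-anchored proteins, was higher in cKO at 5.22 ± 0.53 FPKM against 1.56 ± 0.25 FPKM (mean ± SD, n = 4 each; log2 fold change +1.29 ± 0.11 SE, adjusted p = 9.51e-05). Clca4a, of the family of calcium-activated chloride channel regulators, rose by 0.96 ± 0.16 SE on the log2 scale, Clca3a2 of the same family by 0.69 ± 0.12 SE, and Spred1, an inhibitor of Ras and MAPK signalling, by 0.59 ± 0.10 SE. Cd74, the invariant chain that escorts MHC class II molecules, was lower in cKO at 19.8 ± 4.96 FPKM against 67.1 ± 32.4 FPKM (log2 fold change -1.63 ± 0.26 SE, adjusted p = 0.0287). The others that fell were the lipid droplet enzyme Hsd17b13 (-0.87), the carboxylesterase Ces2b (-0.86), the fatty acid desaturase Fads3 (-0.63) and the membrane metalloproteinase Mmp15 (-0.63), each with an SE between 0.10 and 0.14. The 3 remaining calls, chosen after their values were seen, were the rises of 3930402G23Rik, Gm29051 and Gm45042. Tbl1xr1 had a log2 fold change of +0.47 and did not pass the threshold (adjusted p = 0.0506).

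4 of 35 gene lists were called between genotypes on water. The lists of the cell cycle and the type I interferon response were higher, with median log2 fold changes of +0.26 and +0.36. The lists of the nuclear-encoded respiratory chain and of glycolysis and hypoxia were lower, at -0.22 and -0.27. No call held with an estimated correlation, where the adjusted p of these lists were 0.495, 0.853, 0.495 and 0.0734. None of their members was called over all genes. Adjusted over the list alone, 10 of 30 cell cycle genes were higher, with Top2a at +0.52 ± 0.11 SE and Ccne2 at +0.63 ± 0.16 SE. Likewise 11 of 22 glycolysis and hypoxia genes were lower, with Hk2 at -0.35 ± 0.08 SE and Egln3 at -0.51 ± 0.13 SE. Adjusted over the list alone, 8 of 31 respiratory chain genes were lower, such as Uqcrb at -0.58 ± 0.12 SE, and 1 of 25 type I interferon genes was higher, with Oas2 at +1.07 ± 0.24 SE. Across genes, which are not independent replicates, the fold changes correlated with GC content at a Spearman rho of -0.52 and with gene length at 0.20. With a GC correction 9 genes were called, 7 of them among the 12. The count of 12 genes was 2 without cKO replicate 3 or 4, 111 without cKO_DSS replicate 2, 29 with limma voom and 20 without cKO_DSS replicates 3 and 4.

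After DSS, 491 genes differed between genotypes, 269 higher and 222 lower in cKO. Among the large rises were Ly6d of the LY6 family (12.3 ± 4.78 against 1.498 ± 0.97 FPKM, mean ± SD, n = 4 each; log2 fold change +2.42 ± 0.28 SE, adjusted p = 0.000668) and the metallothionein Mt1 (+1.97 ± 0.33 SE). Also higher was the tight junction protein Cldn4 (58.6 ± 12.5 against 17.004 ± 1.85 FPKM; +1.71 ± 0.17 SE). Nt5c1a, a cytosolic nucleotidase, rose by 2.16 ± 0.31 SE, Aldh1a3, which makes retinoic acid, by 1.46 ± 0.23 SE, and Clca4a by 1.39 ± 0.16 SE. Ly6c1 (+1.43), Ly6m (+1.33), Fosb (+1.28) and Klf2 (+1.24) were also higher. Large falls included the cytochrome P450 Cyp2c68 (14.8 ± 4.74 against 52.0 ± 9.02 FPKM; -1.79 ± 0.22 SE), and the defensin Defb37 (-1.72). The posterior homeobox gene Hoxd13 (9.30 ± 3.11 against 28.6 ± 2.92 FPKM; -1.58 ± 0.20 SE), the sugar phosphate transporter Slc37a2 (-1.35), the clock repressor Nr1d1 (-1.32) and the elastase Cela1 (-1.04) fell too. Eno1b fell by 1.65 while its near-identical parent gene Eno1 rose by 0.44, so reads shared between them leave both values uncertain.

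15 of 35 lists were called between genotypes after DSS, and none held with an estimated correlation (adjusted p between 0.0745 and 0.587). In the list of fetal-like and YAP-linked regeneration, genes that colonic epithelium expresses during repair, 8 of 20 measured members rose and none fell (12 adjusted over the list alone; median log2 fold change +0.45; adjusted p = 0.0745 with an estimated correlation). They included Ly6d, Cldn4, Plaur (+0.93 ± 0.20 SE) and Il1rn (+0.65 ± 0.13 SE). In the immediate early and handling stress list, which holds genes that respond within minutes to growth factors and to tissue handling, 8 of 20 rose and none fell (14 adjusted over the list alone; median +0.53; adjusted p = 0.266 with an estimated correlation). Among them were Egr1 (+1.17 ± 0.17 SE), Nr4a1 (+1.06 ± 0.22 SE) and Fos (+0.77 ± 0.16 SE). Of 31 respiratory chain genes, 6 fell and none rose (13 adjusted over the list alone; adjusted p = 0.285 with an estimated correlation), including Cox6c (-1.65 ± 0.34 SE), Ndufa1 (-1.12 ± 0.21 SE) and Ndufv2 (-0.35 ± 0.08 SE). In the list of MHC class II and the interferon gamma response, 2 of 24 fell, Ido1 (-0.87 ± 0.16 SE) and Cxcl9 (-0.77 ± 0.18 SE), with an adjusted p = 0.293 with an estimated correlation. In the epithelial antimicrobial list 2 of 20 fell, the NADPH oxidase Nox1 (-0.98 ± 0.16 SE) and the acute phase protein Saa1 (-0.91 ± 0.16 SE), with an adjusted p = 0.297 with an estimated correlation.

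The goblet cell, tuft cell, tight junction and inflammatory cytokine lists were called higher with 1, 2, 2 and 1 members past the threshold, such as Bcas1 (+0.61), Sh2d7 (+0.58), Cldn23 (+0.52) and Socs3 (+0.93). The enteroendocrine cell, T cell and unfolded protein response lists were called higher, and the cholesterol synthesis and ribosomal protein lists lower, with no member past the threshold. The fibroblast and matrix list was called lower with Sparc (-0.69) past the threshold. All 10 of these calls were lost with an estimated correlation (adjusted p between 0.261 and 0.587). Outside the called lists, Irs2, a FOXO target that relays insulin signals, rose by 0.90 ± 0.14 SE. The iron exporter Slc40a1 (-0.71) and the stem cell marker Smoc2 (-0.61) fell. Of the xenobiotic metabolism genes the drug exporter Abcb1a rose (+0.64) and the alcohol dehydrogenase Adh1 fell (-0.74). The absorptive colonocyte list went both ways, with Clca4a and Muc3a (+0.43) higher and Slc37a2 and Trpm6 (-0.57) lower, and was not called.

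Libraries cKO_DSS 3 and 4 stood apart from the rest on the second principal component, at -33.9 and -32.2, and their deviations from the gene means correlated with GC content at 0.399 and 0.388, against -0.255 and -0.375 in cKO_DSS 1 and 2. Without them, 32 genes differed between genotypes after DSS, 26 of which were among the 491. Without control_DSS 1, 2 or 4 the counts were 148, 91 and 253. Without cKO_DSS 1, 3 or 4 they were 877, 105 and 157, and without control 4 and control_DSS 2 the count was 115. In the 8 samples of this comparison alone 96 genes were called.

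**Figure D2:**
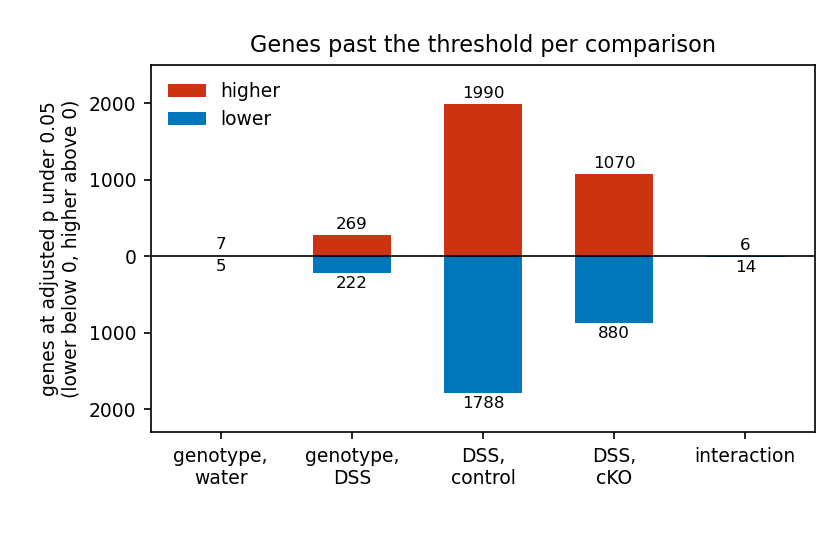
Number of genes (y axis) past the threshold in each comparison (x axis), with genes higher in cKO or after DSS above 0 and lower genes below 0. The counts run from 12 genes between genotypes on water to 3778 with DSS in control. With a GC correction, not drawn here, the counts with DSS were 2590 in control and 2539 in cKO.

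DSS against water in control mice gave 3778 genes, 1990 higher and 1788 lower. Large rises included interferon-induced genes and the Y-linked Ddx3y (+2.32) and Eif2s3y (+2.14). The GTPase Iigp1 went from 1.73 ± 0.76 to 42.1 ± 4.79 FPKM (mean ± SD, n = 4 each; log2 fold change +4.03 ± 0.26 SE, adjusted p = 6.79e-07) and Ifit2 from 9.53 ± 4.31 to 103 ± 10.8 FPKM (+3.43 ± 0.33 SE). The GTPases Tgtp1 (+2.78 ± 0.22 SE) and Igtp (+2.33 ± 0.14 SE) and the chemokine Cxcl10 (+2.58 ± 0.28 SE) followed. The tryptophan-degrading enzyme Ido1 (+2.36 ± 0.16 SE), Rsad2 (+2.28 ± 0.27 SE) and Slfn5 (+2.11 ± 0.26 SE) rose as well. In the list of MHC class II and the interferon gamma response 17 of 24 members rose and none fell (17 adjusted over the list alone; median +1.04; adjusted p = 0.00441 with an estimated correlation). In the type I interferon list 22 of 25 rose and none fell (23 adjusted over the list alone; median +1.26), with Mx2 at +1.86 ± 0.18 SE, and this call was lost with an estimated correlation (adjusted p = 0.214). Large falls included the ribosomal protein gene Rpl7a (-2.51 ± 0.57 SE), Naa38 (-1.97 ± 0.48 SE), Edf1 (-1.69 ± 0.39 SE), Lsm7 (-1.52 ± 0.27 SE) and the respiratory chain gene Uqcr11 (-1.41 ± 0.29 SE), together with the cytochrome P450 Cyp4b1 (-1.72 ± 0.42 SE).

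Another 12 lists were called with DSS in control, none of them with an estimated correlation (adjusted p between 0.101 and 0.615). The fibroblast and matrix list rose with 6 of 9 members higher, such as the collagen Col3a1 (0.36 ± 0.08 to 2.21 ± 0.30 FPKM; +1.24 ± 0.11 SE), Sparc (+1.43 ± 0.17 SE) and Dcn (+1.04 ± 0.13 SE). The monocyte and macrophage list rose with 4 of 7 higher and 1 lower, such as Lyz2 (+1.15 ± 0.25 SE) and C1qb (+0.79 ± 0.16 SE). The regeneration list rose with 8 of 20 members higher and 1 lower, led by Ly6a (+1.47 ± 0.20 SE) and Ereg (+1.22 ± 0.18 SE). The antimicrobial list rose with 10 of 20 higher, such as Steap4 (+1.10 ± 0.17 SE) and Nlrp6 (+0.59 ± 0.08 SE), and 2 lower, among them Saa1 (-0.82 ± 0.16 SE). Cell death (10 higher and 2 lower of 25; Cdkn1a -0.52) and autophagy and lysosome (7 of 23 higher; Irgm1 +1.72, Map1lc3b +0.48) were called higher. So were FOXO targets (7 of 19 higher; Pdk4 +1.26, Txnip +0.54) and goblet cell genes (4 higher and 1 lower of 22; Sytl2 +0.65, Gfi1 -0.62). Ribosomal proteins (15 of 40 lower; Rps23 -1.04) and cholesterol synthesis (9 lower and 1 higher of 27; Mvd -0.97, Fdps -0.96) were called lower. So were glycolysis and hypoxia (6 lower and 1 higher of 22; Egln3 -0.66, Vegfa -0.65) and the mitochondrially encoded genes (2 of 15 lower; mt-Nd1 -0.75). In lists that were not called, the Wnt targets Axin2 (-1.04 ± 0.14 SE) and Ascl2 (-1.19 ± 0.18 SE) and the replication genes E2f1 (-0.94 ± 0.15 SE) and Mcm7 (-0.55 ± 0.10 SE) fell. The enteroendocrine list went both ways, with Nts at +1.202 and Chga at -0.86. In the immediate early list Hspa1b (+1.52) and Hspa8 (+0.75) rose while Nr4a1 (-1.35) and Junb (-1.28) fell. Among mTOR complex members Deptor rose (+0.53) and Akt1s1 (-0.86) and Telo2 (-0.37) fell.

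The water and DSS libraries also differed in sex-linked and clock genes. Xist, which is expressed from the inactive X chromosome of female cells, fell from 45.4 ± 14.1 to 5.12 ± 10.2 FPKM with DSS in control and from 78.1 ± 24.9 to 0.00707 ± 0.00644 FPKM in cKO. The Y-linked Ddx3y rose by 2.32 ± 0.56 SE and 2.65 ± 0.56 SE on the log2 scale. No read of 4 Y-linked genes was counted in control 3, cKO 3 and cKO 4, while the DSS libraries held 2681 to 4533 such reads. Of 10 clock genes, chosen after their values were seen, 8 were called with DSS in control and 10 in cKO, and control 4, on water, had 1.52 FPKM of Dbp against 13.8 to 28.4 FPKM in the other control libraries on water. Without control 4 and control_DSS 2, 1466 genes were called with DSS in control, and 1389 of these were among the 3778. With the level of the Y-linked genes as a covariate 10 genes were called in control and none in cKO, where 1459 had an unadjusted p under 0.05 in limma. Across genes the DSS fold changes in control correlated with GC content at a Spearman rho of -0.53, and after a GC correction 2590 genes were called, 1970 of them among the 3778. In the lost genes the median absolute log2 fold change went from 0.43 to 0.19 and the median SE from 0.13 to 0.0984. The DSS fold changes also correlated with gene length, at a Spearman rho of 0.23 in control and 0.13 in cKO, so shorter genes tended to fall. After a length correction 3591 genes were called in control, 3180 of them among the 3778.

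**Figure D3:**
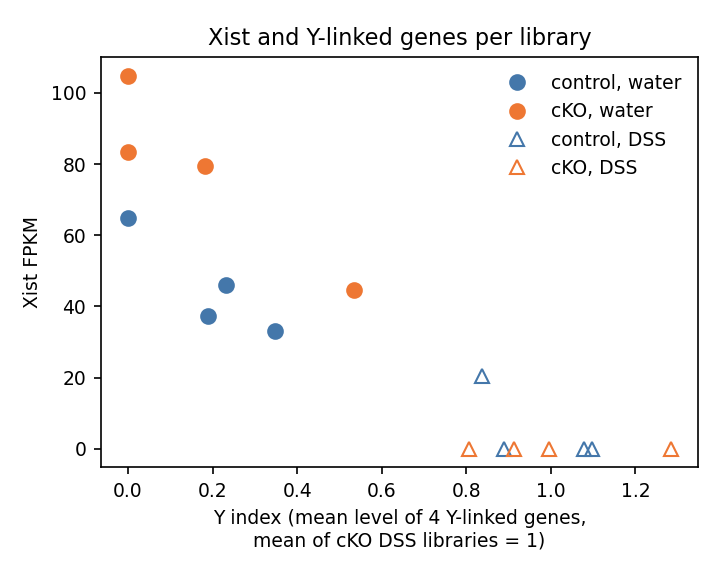
Xist FPKM (y axis) against the Y index, the mean level of Ddx3y, Uty, Kdm5d and Eif2s3y relative to the cKO DSS libraries (x axis), with 1 point per library. The 8 water libraries lie between 33.2 and 105 FPKM of Xist, and the DSS libraries lie at or under 20.5 FPKM with a Y index of 0.81 to 1.28.

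**Figure D4:**
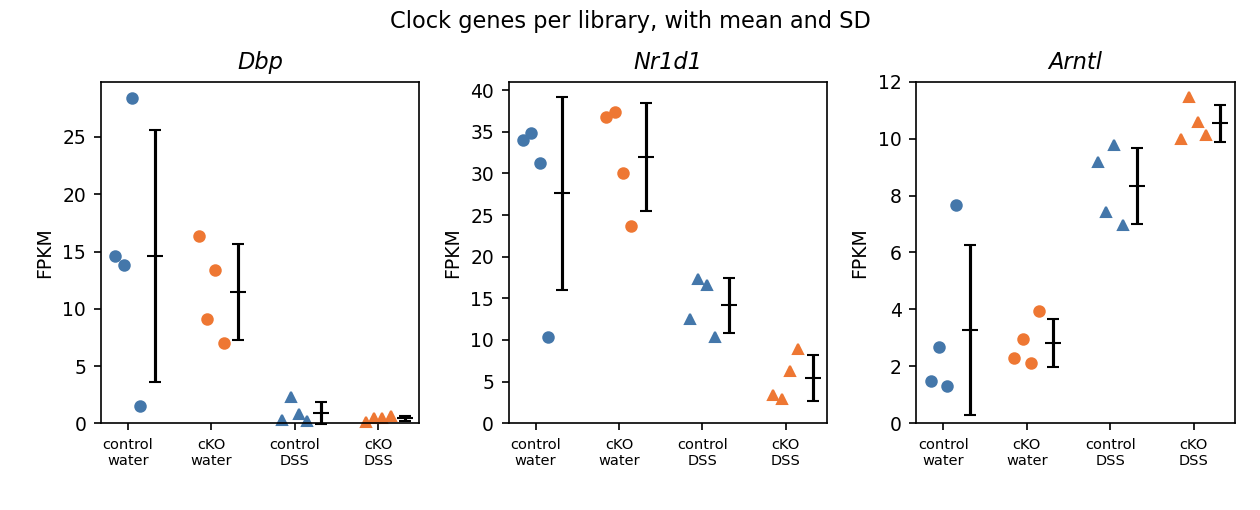
FPKM (y axes) of the clock genes Dbp, Nr1d1 and Arntl in each library of the 4 groups (x axes), with the group mean and SD (n = 4) beside the points. Control 4, on water, lies at 1.52, 10.4 and 7.66 FPKM, among the DSS libraries of control mice or close to them.

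DSS against water in cKO mice gave 1950 genes, 1070 higher and 880 lower. With the GC correction 2539 genes were called in cKO and 2590 in control, so the counts of 1950 and 3778 do not rank the 2 responses. Iigp1 rose from 2.81 ± 1.21 to 29.2 ± 7.38 FPKM (mean ± SD, n = 4 each; log2 fold change +3.03 ± 0.26 SE, adjusted p = 2.21e-05) and Ifit2 by 2.81 ± 0.33 SE. Ly6d rose from 1.01 ± 0.59 to 12.3 ± 4.78 FPKM (+2.70 ± 0.28 SE), Nt5c1a by 2.04 ± 0.31 SE and the clock-linked repressor Nfil3 by 2.03 ± 0.26 SE. The fatty acid receptor Ffar4 (+1.98 ± 0.20 SE), Trim30d (+1.92 ± 0.31 SE) and Tgtp1 (+1.86 ± 0.22 SE) also rose. Large falls included clock output genes and clock repressors. Dbp (11.5 ± 4.22 to 0.43 ± 0.21 FPKM; -3.08 ± 0.55 SE), Tef (-2.57 ± 0.45 SE), Nr1d1 (-2.44 ± 0.35 SE), Nr1d2 (-1.74 ± 0.34 SE) and Ciart (-1.63 ± 0.35 SE) fell. So did the ATP synthase gene Atp5k (-2.14 ± 0.46 SE), the ribosomal protein genes Rpl38 (-1.92 ± 0.35 SE) and Rpl41 (-1.64 ± 0.33 SE) and the actin-binding protein Cnn3 (-1.62 ± 0.21 SE).

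26 of 35 lists were called with DSS in cKO, and 7 held with an estimated correlation. In the list of MHC class II and the interferon gamma response 19 of 24 genes rose, such as Igtp (+1.60) and Tap1 (+1.22), with an adjusted p = 0.000924 with an estimated correlation. In the regeneration list 12 of 20 rose, such as Plaur (+1.53) and Cldn4 (+1.37), with an adjusted p = 0.00797 with an estimated correlation. Tight junction genes rose in 8 of 25 cases, F11r by 0.35, with an adjusted p = 0.0343 with an estimated correlation. Of 30 cell cycle genes 16 fell, such as Mcm6 (-0.81) and Mcm7 (-0.80), with an adjusted p = 0.0373 with an estimated correlation. Of 14 enteroendocrine genes 9 rose, such as Nts (+1.45), Tph1 (+1.07) and Gcg (+1.03), with an adjusted p = 0.0373 with an estimated correlation. Of 10 genes of inflammatory cytokines and NF-kB feedback 6 rose, such as Socs3 (+0.94), Nfkb2 (+0.66) and Tnfaip3 (+0.55), with an adjusted p = 0.0390 with an estimated correlation. Of 23 autophagy and lysosome genes 5 rose and 1 fell, with Irgm1 at +0.89 and Ctsl at +0.70 and an adjusted p = 0.0390 with an estimated correlation. Adjusted over the list alone, the counts in the direction of the call were 20, 15, 11, 23, 11, 8 and 5.

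For the other 19 lists the adjusted p with an estimated correlation lay between 0.0685 and 0.430. Higher were the type I interferon response (21 of 25; Mx2 +1.52), goblet cells (13 of 22 higher and 1 lower; Sytl2 +1.05, Spdef +0.79, Galnt12 +0.76, Klk1 +0.66) and the unfolded protein response (8 of 22; Hspa5 +0.79, Hyou1 +0.75, Xbp1 +0.54). So were cell death (7 higher and 1 lower of 25; the gasdermins Gsdmc2 +1.28 and Gsdmc4 +1.18, which are close paralogs), fibroblast and matrix (5 of 9; Col3a1 +0.74) and FOXO targets (6 higher and 1 lower of 19; Pdk4 +1.29). Lists of mTORC2 substrates and partners (3 higher and 1 lower of 22; Sgk1 +0.90), T cells (2 of 15; Gzmb +0.94) and antimicrobial genes (6 higher and 3 lower of 20; Duoxa2 +1.13, Nlrp6 +0.53, Saa1 -0.93) were called higher as well. The same held for glycolysis and hypoxia (3 of 22; Hk2 +0.86), fatty acid oxidation (5 of 24; Plin2 +0.41), immediate early genes (6 of 20; Hspa1b +1.44, Nr4a2 +0.85) and sex-linked genes (4 higher and Xist lower). Lower were cholesterol synthesis (19 of 27; Hmgcs1 -1.25, Scd2 -0.93, Fasn -0.74), mitochondrially encoded genes (8 of 15; mt-Cytb -1.28, mt-Nd1 -1.11) and ribosomal proteins (9 of 40; Rpl5 -0.66, Rpl4 -0.48). The other lists called lower were stem cell and crypt base genes (6 lower and 1 higher of 17; Axin2 -1.35, Ascl2 -1.17), the respiratory chain (4 of 31; Cox6c -1.22, Ndufa1 -0.73) and xenobiotic metabolism (6 lower and 2 higher of 31; Abcc3 -0.47, Cyp2c66 +0.68). The share of reads from mitochondrial genes was 11.2 ± 3.13% in cKO libraries on water and 5.96 ± 1.07% after DSS. Many ribosomal protein genes have near-identical pseudogene copies that can take their reads, so their values are uncertain.

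**Figure D5:**
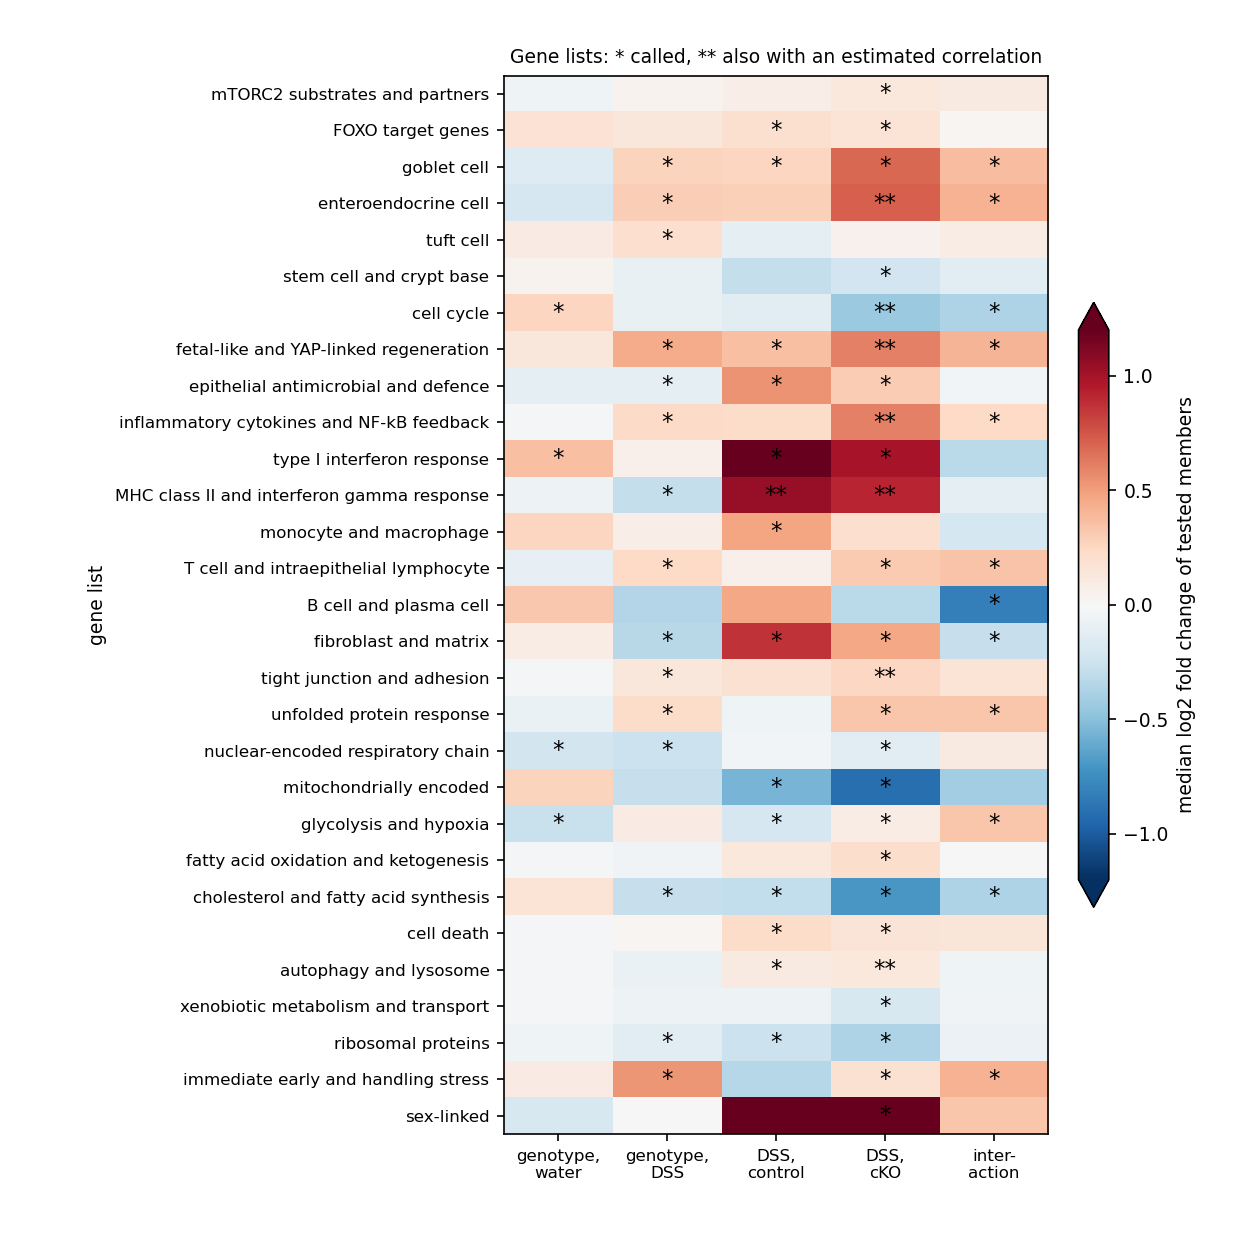
Median log2 fold change of the tested members (colour, saturating at the ends of the bar) of each list (y axis) called in at least 1 of 5 comparisons (x axis). Single stars mark calls and double stars calls that held with an estimated correlation, 7 with DSS in cKO and 1 with DSS in control.

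Whether the genotypes responded differently to DSS was tested with the interaction, the DSS response in cKO minus that in control. It was past the threshold for 20 genes, 6 higher and 14 lower in cKO, and 3074 had an unadjusted p under 0.05. Hk2, the hexokinase that commits glucose to glycolysis, had a DSS response higher in cKO (difference of log2 fold changes +0.81 ± 0.12 SE, n = 4 per group, adjusted p = 0.0239), as did Yif1b (+1.19 ± 0.21 SE) and the nucleotide transporter Slc17a9 (+0.72 ± 0.13 SE). Hoxd13 was lower by 1.81 on this scale (-1.81 ± 0.28 SE). The others with the smallest p were Polr2k (-2.18 ± 0.38 SE), Pcbd2 (-1.33 ± 0.24 SE), the ERM protein Rdx (-1.06 ± 0.18 SE), Nucks1 (-0.81 ± 0.14 SE), Septin10 (-0.68 ± 0.10 SE) and Tbl1xr1 (-0.67 ± 0.12 SE). Of 35 lists 12 were called, and none held with an estimated correlation (adjusted p between 0.154 and 0.685). The lists whose difference was higher in cKO included glycolysis and hypoxia (9 of 22 higher and 2 lower adjusted over the list alone), enteroendocrine and goblet cells and the unfolded protein response. Those lower included the cell cycle (6 of 30 adjusted over the list alone) and cholesterol synthesis. A GC correction gave 9 genes, 7 of them among the 20, and leaving out cKO_DSS 3 and 4 together left none, with 1271 at an unadjusted p under 0.05 in limma.

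Across 13255 genes, which are not independent replicates, the DSS fold changes of the genotypes correlated at a Pearson r of 0.43 (jackknife SE over libraries 0.18). Both comparisons called 881 genes, 855 in the same direction: 553 higher, where independent lists of these sizes would share 161, and 302 lower, where they would share 119. In both genotypes the water and DSS libraries also differed in clock genes and in the Y index. The mean Y index went from 0.19 to 0.98 in control and from 0.18 to 1 in cKO. The r and the sharing beyond independence therefore cannot be assigned to DSS alone. The genotype fold changes on water and after DSS had a Pearson r of -0.05 (jackknife SE 0.20), within error of 0. Without cKO_DSS 3 and 4 these r were 0.629 for the DSS responses and 0.203 for the genotype differences. Even so, 6 genes were called in both, all in the same direction: Clca4a, Ly6g6c and Hsd17b13, and, chosen after their values were seen, 3930402G23Rik, Gm29051 and Gm45042. Hsd17b13 was lower in cKO on both, by -0.87 on water and -0.58 after DSS, and Ly6g6c was higher by +1.29 and +1.06.

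Most markers of other cell types were near the floor of the data, with a median over each list's genes at or under 0.58 FPKM in every group for neutrophils, monocytes and macrophages, B cells, fibroblasts, smooth muscle, endothelium, enteric neurons and glia, pancreas and mesenteric fat. T cell markers had medians of 0.996 to 1.33 FPKM and small intestine markers of 0.19 to 3.21 FPKM. Single markers were higher: Ctss of the monocyte and macrophage list had means of 131 to 185 FPKM, Cela1 of the pancreas list of 49.5 to 103 FPKM and Igkc of the B cell list of 8.396 to 21.6 FPKM. Ly6g, the 1 neutrophil marker of 22 to pass the filter, had a mean of 35.4 to 55.7 FPKM while the median over that list was at or under 0.03 FPKM. The smooth muscle, small intestine, posterior Hox, ferroptosis, absorptive colonocyte and mTOR complex lists were called in none of the 5 comparisons, although single members moved, such as Tpm2 (+0.87) and Hoxd11 (-0.57) between genotypes after DSS. Neutrophil, endothelium, enteric neuron, pancreas and fat lists had fewer than 5 members past the filter and were not tested.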

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

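Of the tests below, those chosen after the result was seen were the correlation of Xist with Y-linked genes, the counts of water libraries with few Y-linked reads and with low Dbp, the spread of the GC correlations, the exact tests of these correlations between groups, the shares of calls kept after the GC correction, the product of the GC correlations, and the errors of the correlations with the slope on the Y index, with the use of these errors in reading them. The others were written down before they were run.

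A gap test within each group of 4 libraries marked 6 of 88 groups, where chance marks about 5%. In control_DSS 2 Xist stood at 20.5 FPKM and in the other control_DSS libraries at or under 0.03 FPKM. Mt1 was 201 FPKM in control 3 and 165 FPKM in control_DSS 4, Nr1d1 was 10.4 FPKM in control 4, the correlation with GC content was 0.0178 in control_DSS 3, and control 1 lay at 10.99 on the second principal component.

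Of the 20 genes past the threshold of the interaction, the 10 with the smallest p are given here: Hk2 (+0.81), Yif1b (+1.19) and Slc17a9 (+0.72) had a response higher in cKO, and Septin10 (-0.68), Hoxd13 (-1.81), Nucks1 (-0.81), Rdx (-1.06), Polr2k (-2.18), Tbl1xr1 (-0.67) and Pcbd2 (-1.33) were lower. It marked 12 lists, given as median differences of log2 fold changes, and none of these calls held with an estimated correlation (adjusted p between 0.154 and 0.685). Higher in cKO were the lists of goblet cells (+0.37), enteroendocrine cells (+0.42), regeneration (+0.41), inflammatory cytokines (+0.23), T cells (+0.34), the unfolded protein response (+0.34), glycolysis and hypoxia (+0.33) and immediate early genes (+0.42). Lower were the lists of the cell cycle (-0.37), B cells (-0.82), fibroblasts (-0.28) and cholesterol synthesis (-0.37).

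Counts were compared with all 35 splits of the 8 libraries of a comparison into 4 and 4, the real one included, and with 100 splits for the interaction. As many genes as in the real split were called in 1 split for the genotypes on water (highest other count 4), 1 for DSS in control (1), 1 for DSS in cKO (2), 3 for the genotypes after DSS (578) and 2 for the interaction (2457). The other 2 splits after DSS exchanged control_DSS 3 with cKO_DSS 1 or 2 and called 578 and 553 genes, so a grouping other than genotype could give a count as large as 491. They set control_DSS 3, with a GC correlation of 0.0178, beside cKO_DSS 3 and 4, at 0.399 and 0.388. For lists, the real count was reached in 35 of 35 splits on water, so 4 called lists could arise from any grouping of these libraries, and in 12 of 100 for the interaction. It was reached in 1 split of 35 each for the genotypes after DSS, DSS in control and DSS in cKO, with highest other counts of 14, 12 and 23.

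Xist fell and Y-linked genes rose with DSS in both genotypes, and 2 explanations were weighed: cells of female and male mice in different shares, and DSS acting on cells of 1 sex. Within the 8 water libraries the deviations of Xist and of the Y index from their group means had a Pearson r of -0.931 (exact permutation p = 0.00694; Spearman rho -0.886, exact p = 0.0104; r = -0.856 without the 2 farthest libraries), which fits a mixture of sexes, and 3 water libraries had fewer than 3 Y-linked reads, which argues against 1 sex. X genes that escape inactivation left it open (higher of the 2 median log2 fold changes with DSS 0.0142). Across called autosomal genes, the fold changes with DSS were correlated with the slope on the Y index within water groups. Pearson r was 0.0540 in control (jackknife SE over the water libraries 0.346) and 0.325 in cKO (SE 0.0597). By the limit written beforehand, the value in control went against a share due to sex. With its SE, used after the values were seen, the value in control was too uncertain to decide. The value in cKO fits a share due to sex among the called genes. Over all autosomal genes r was lower, 0.0203 in control and 0.160 in cKO. No DSS library was left out for these SE, so they cover only part of the error. With the Y index as a covariate the median absolute log2 fold change of the called genes went from 0.49 to 0.26 in control and from 0.54 to 0.45 in cKO, while the median SE went from 0.13 to 0.24 and from 0.13 to 0.25. The calls in control then went from 3778 to 10. DSS and sex were nearly inseparable in this design, so for single genes other than the Y-linked ones and Xist the share due to sex stays open.

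Clock genes differed between water and DSS libraries, and the explanations weighed were collection at different times of day, GC content and an effect of DSS on the clock. For Usp2 and Wee1, clock-linked genes not looked at before, the higher of the 2 median log2 fold changes with DSS was -0.67. This fits a difference in phase but would also follow if DSS changed the clock, so it does not separate these explanations. Tspan4, the other gene of this test, did not pass the filter. After the GC correction 10 of 10 clock genes were called with DSS in cKO. The fold changes there had little GC trend to remove (Spearman rho 0.0546), so the test could hardly have come out otherwise. It shows only that a GC trend was not needed for the clock calls in cKO. DSS in control, where rho was -0.53, was not tested in this way, so GC content stayed open there. In Dbp 1 water library, control 4, lay in the range of the DSS libraries, so an effect of DSS on the clock stayed open.

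Fold changes between genotypes followed GC content, and the explanations weighed were yield that depends on GC content in single libraries and an effect of genotype on GC-rich transcripts. Within cKO_DSS the correlations with GC content spanned 0.774, which fits a difference between single libraries. On water the libraries separated by genotype, at 0.190 to 0.498 in control and -0.226 to 0.00519 in cKO (exact permutation p = 0.0286, the smallest possible), and DSS in control also gave an exact p = 0.0286. After DSS the genotypes gave an exact permutation p = 0.171, and DSS in cKO gave an exact permutation p = 0.543. The product of the correlations of the genotype fold changes on water and after DSS was -0.196, a restatement of values already seen, so an effect of genotype stayed open. On water 7 of the 12 genotype calls were kept after the GC correction (9 called). After DSS 80.2% of the 491 genotype calls were kept with it (548 called), and 79.8% after the GC and length correction. The GC trend that these corrections remove was thus not needed for most of the 491 calls. The limit for this reading was set after the values were seen, and effects of GC content outside that trend were not tested. Of the 20 interaction calls 35% were kept, 7 of 20 with 9 called; among the 13 lost ones the median absolute log2 difference went from 0.94 to 0.73 and the median SE from 0.17 to 0.15, so GC content could account for part of these differences, and 0.73 of the 0.94 remained.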

How the results depend on the processing

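Of 200 named gene results past the threshold, 15 passed it under every alternative run for them and 146 with any 1 library left out, and of 71 called lists these were 7 and 48. The GC and length corrections, the Y index covariate and the 2 sets of left-out libraries were chosen after seeing the data. Where no cause is named below, the cause was not tested. With 13911824 to 16414916 reads per library, low genes are limited by depth. The 8 samples alone and the fold limit were run for counts of genes only. The stricter filter and voom were not run for lists.

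Between genotypes on water the count of 12 became 2 with no filter, 20 with quantile normalization, 20 with a median shift, 267 with sample quality weights, 23 with the Y index covariate, 20 without cKO_DSS 3 and 4, 6 in the 8 samples alone, 29 with voom and 5 with a fold limit. Leaving out single libraries gave 2 to 111: 4 without control 1, 6 without control 2, 4 without cKO 2, 2 without cKO 3 or cKO 4, 3 without control_DSS 1, 111 without cKO_DSS 2, 5 without cKO_DSS 3 and 3 without cKO_DSS 4.

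After DSS the genotype count of 491 became 209 with no filter, 3485 with weights, 32 without cKO_DSS 3 and 4, 115 without control 4 and control_DSS 2, 96 in the 8 samples alone and 84 with a fold limit (32 higher and 52 lower, against 269 and 222). Single libraries gave 91 to 877: 148, 91 and 253 without control_DSS 1, 2 and 4, and 877, 105 and 157 without cKO_DSS 1, 3 and 4.

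For DSS in control 3778 became 10 with the Y index covariate, 1466 without control 4 and control_DSS 2, 318 with a fold limit (139 higher and 179 lower, against 1990 and 1788), and 2236 to 4261 with single libraries left out (2513 without control 3, 2461 without control 4, 2236 without control_DSS 1, 2445 without control_DSS 2). For DSS in cKO 1950 became 3060 with weights, 279 with a fold limit and 0 with the Y index covariate, where limma gave 1459 genes at an unadjusted p under 0.05; voom without the covariate gave 2014. With this covariate the called genes had a median absolute log2 fold change of 0.26 in control (0.49 without it) and 0.45 in cKO (0.54), and a median SE of 0.24 (0.13) and 0.25 (0.13), so both smaller folds and wider errors ended calls. In control 16 lists were called with it, 8 of them among the 14, and 1 of the 14 reversed.

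The interaction count of 20 became 4 with no filter, 46 with the stricter filter, 11 with quantile normalization, 36 with a median shift, 3728 with weights, 9 with the GC correction, 7 with GC and length, 68 with voom and 11 with a fold limit. It was 0 without cKO_DSS 3 and 4 and 0 without control 4 and control_DSS 2 (1271 and 1969 at an unadjusted p under 0.05 in limma). Single libraries gave 0 to 1268, and each of the 16 moved it by over 1.5 times: 1268 without cKO_DSS 2, 392 without cKO_DSS 1, 131 without control_DSS 3, 0 without control_DSS 2, control_DSS 4 or cKO_DSS 4, and 1 to 10 without any other. Of the 20, 30% were higher in cKO, against 52.8% with a median shift and 18.2% with quantile normalization.

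Rictor after DSS (-0.40) passed the threshold with weights (-0.51), length correction (-0.39), GC and length correction (-0.35) and voom (-0.54), and lay between -0.49 and -0.32 with single libraries left out, passing without control_DSS 3 (-0.49) and cKO_DSS 1 (-0.46).

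Called lists on water went from 4 to 10 with the GC correction, 11 with GC and length, 0 with an estimated correlation, 1 with fry and 4 to 9 with single libraries left out (7 without control 1, 9 without cKO 1, 7 without cKO 2, 9 without cKO 3). The 15 after DSS became 0 with an estimated correlation. For DSS in control 14 became 9 with quantile normalization, 1 with an estimated correlation and 7 to 15 with single libraries left out (7 without control 1, 8 without control 2, 7 without control_DSS 3, 9 without cKO_DSS 2). For DSS in cKO 26 became 15 with the Y index covariate and 7 with an estimated correlation, and the 12 of the interaction became 0 with the latter. Fry called 13 lists between genotypes after DSS (10 of the 15), 13 with DSS in control (10 of the 14), 25 with DSS in cKO (24 of the 26) and 9 for the interaction (8 of the 12). It does not compare a list with other genes, so it does not make up for the calls lost with an estimated correlation.

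With the Y index covariate the following reversed and lost their calls. With DSS in control they were Ddx3y (-0.93), Uty (-0.21), Sytl2 (-0.14) and the goblet cell list (adjusted p = 0.0617). With DSS in cKO the genes were Ddx3y (-0.75), Uty (-0.34) and Tnfaip3 (-0.0204). The lists in cKO were the respiratory chain (adjusted p = 0.277), xenobiotic metabolism (0.0810), immediate early genes (0.706) and sex-linked genes (0.0514). Ddx3y and Uty are part of the Y index, and the sex-linked list holds genes of it. Ddx3y, Uty and this list were thus adjusted for their own level, so their reversals are no test of their calls.

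Without cKO_DSS 3 and 4 the Pearson r between the DSS responses of the genotypes was 0.629 and that between the genotype differences 0.203.

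Replicate numbers did not pair the libraries throughout: over 24 same-numbered pairs the correlations of deviations ran from -0.199 to 0.2995, 6 over 0.1. The same number was the best partner in 8, among them all 4 pairs of control with cKO_DSS (0.0923 to 0.227). A batch shared by number between some groups therefore stays open. A replicate block gave 2, 429, 3857, 1898 and 13 genes for the genotypes on water and after DSS, DSS in control and cKO, and the interaction, and 8 lists for DSS in control.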

Other observations

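All tests in this part were chosen after the result was seen.

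Spred1, which restrains MAPK signalling, rose in cKO on water (+0.59 ± 0.10 SE, n = 4 per group). Of 10 genes that this pathway induces, chosen after values of several of them were seen, 7 rose in cKO after DSS: Epha2 (+1.07 ± 0.20 SE), Etv4 (+1.02 ± 0.20 SE), Dusp4 (+0.74 ± 0.17 SE), Etv5 (+0.71 ± 0.16 SE), Dusp6 (+0.69 ± 0.16 SE), Spry4 (+0.58 ± 0.13 SE) and Phlda1 (+0.58 ± 0.15 SE). On water 0 of the 10 were called, with Dusp6 at +0.72 ± 0.16 SE, Dusp4 at +0.63 ± 0.17 SE and Phlda1 at +0.51 ± 0.15 SE. Spry2 (+0.16 on water and +0.23 after DSS), Ccnd1 (-0.09 and -0.09) and Epha4 (-0.03 and +0.01) were not called in either comparison. In the same comparison the immediate early and handling stress list, which also holds genes induced by growth factors, had 8 of 20 members higher, and without cKO_DSS 3 and 4 the count of all called genes went from 491 to 32.

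Gm10036, chosen after its values were seen, was 2.09 ± 0.52 FPKM in cKO_DSS libraries and 28.4 ± 12.6 FPKM in control_DSS libraries, against 24.2 ± 14.1 FPKM in control and 40.4 ± 9.27 FPKM in cKO on water (mean ± SD, n = 4 each). It is a processed pseudogene by its annotation, so reads of the parent gene may enter its value, and of 954 pseudogenes that passed the filter 36 were called between genotypes after DSS.

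One hypothesis was that loss of Rictor raises the output of the MAPK pathway. On values corrected for GC content and length, camera with an estimated correlation gave p = 0.000189 on water and p = 0.000162 after DSS, and on the values as reported p = 0.00111 and p = 0.000156, where 7 genes were called after DSS and 6 after the correction. Members of the list had been seen to be higher in cKO before it was taken up, so these p-values are no evidence for the hypothesis, which stays open. On the values as reported p was 0.354 for DSS in control, 0.0246 for DSS in cKO (0.0518 on corrected values) and 0.181 for the interaction.

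Another hypothesis was that alleles linked to the floxed gene differ between the genotypes. Of 38 tested genes within 10 Mb of Rictor 2 were called between genotypes after DSS, 5.26% against 3.70% elsewhere (Fisher exact p = 0.651), and none on water, which leaves it open.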
